A study of Mus musculus with 3 samples.

How the data were processed

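Total RNA of 3 dendritic cell subsets of mouse spleen was measured on Affymetrix mouse arrays of 45101 probe sets, 64 of them controls. Per the labels' protocols, splenic mononuclear cells of healthy female C57BL/6 mice aged 6 to 8 weeks were depleted of T and B cells with magnetic beads, and pDC, CD11b+ cDC and CD8+ cDC were then sorted by flow cytometry. RNA of 5 to 8 mice was pooled per cell type, extracted with RNeasy columns, and 20 ng was made into biotinylated cRNA with 2 rounds of amplification. Each cell type has 1 array and no replicate, so animals, sorts, amplification and hybridization vary together with the cell type.

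The deposited values are 1 intensity per probe set and array on a linear scale, and the submitters' processing notes name Microarray Suite 5 (MAS5), with no version. Detection calls were not used here. Lowest values were 22.7, 22.8 and 22.8 for pDC, CD11b+ cDC and CD8+ cDC, and 1063, 1073 and 1072 probe sets exceeded 65535, the limit of a 16-bit scanner reading. Means without the brightest and dimmest 2% of probe sets were 3314, 3310 and 3309. Sorted by size, the 3 columns differed from their mean by 0.01 (mean absolute log2), and single values recur between arrays, as a step that equalises distributions would leave. MAS5 alone does not make arrays that alike, and any scaling or normalization beyond it is not given in the sources used here, so folds are on the authors' scale as deposited.

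A background level was set from probe sets of genes that spleen cells should not express. It was the 95th percentile of 87 olfactory, vomeronasal, trace amine and taste receptor probe sets, taken on the array where it was highest, which gave 111. On at least 1 array, 5 of these 87 exceeded it. Values below the level were set to it, and log2 was taken. With a gene at the level on 1 array, its fold is a bound.

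Probe sets were named by the platform's gene annotation, checked by gene number against a reference gene table of the mouse assembly GRCm38.p6. A single gene was listed for 34958 probe sets (34754 of them found by number), several genes for 932, and no gene for 9211, of which 9160 were not controls. Symbols are those of the annotation and 0 were updated. Positions in the genome were not used. The 18194 genes were each taken at the probe set with the highest mean log2 signal over the 3 arrays, and 9012 had over 1 probe set. Gene symbol and probe set together identify each value, and levels of different genes were not compared.

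All 3 pairs of cell types were compared. A gene counted as higher at 2-fold or more with the brighter array above background, and as specific to a cell type at 4-fold or more over the brighter of the other 2. No test between cell types was run, since 1 array per cell type gives no spread. Of 642 entries in 29 gene lists, 590 were matched and 52 were not analysed here. For each list, the members 2-fold higher and lower were counted among members above background on either array. The median log2 difference is given with a 95% binomial (order statistic) interval from 6 members on. From 5 members on, its percentile was taken among 10000 random lists of the same size, matched on mean log2 signal in 20 bins with seed 20150. The interval and the percentile describe genes on these arrays, not animals. Many lists overlap, so a gene can be counted in several of them and their counts are not separate evidence. Of the pDC markers, Bst2 and Irf7 are also in the interferon-stimulated list, and Ly6d and Blnk in the lymphoid-associated list. Cd4 and Cd8a are in the lymphoid-associated list and in a cDC marker list. The MHC class II, chemokine, transcription factor, Toll-like receptor, lectin, costimulatory and actin lists also repeat marker genes. The entry Clec6a was matched to the same gene as Clec4n.

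The gene lists, the size rule, the background rule, the rule for named genes and the alternatives were chosen before the data were examined, except where a part of the closing section says otherwise. The named genes of a comparison are up to 10 per direction with the largest log2 difference among genes with at least 2 probe sets above background, all 2-fold or more in that direction, and the brightest array at 4 times background or more. To these were added, of each list, up to 4 members per direction with the largest differences and members that went against the list's name. Itgam and Cd8a, whose proteins name the cDC sorts, were added whatever their values. So were Cd4, Itgax, Siglech, Bst2 and Ptprc, as possible sort markers. Ly6c2 was not analysed here. For genes specific to a cell type, up to 10 were taken by the same conditions at 4-fold.

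Error within the arrays was gauged from genes with a second probe set above background. Log2 differences of the 2 probe sets differed with an SD of 0.86 for pDC and CD11b+ cDC, 0.89 for pDC and CD8+ cDC and 0.74 for the cDC subsets. Of genes called by the first probe set, the second called 69.0%, 68.0% and 60.8% in the same direction and 3, 5 and 4 genes in the opposite one. The method was tested on simulated data with noise drawn from these differences, divided by the square root of 2. There 6.31%, 7.67% and 4.68% of unchanged genes passed the 2-fold rule. Of 50 genes per pair changed by 1.5 (log2), 96%, 82% and 94% were recovered in their direction. The noise comes from probe sets on the same arrays, over all genes, strongly changed ones included. It covers probe design, not animals, sorts, amplification or differences between hybridizations. The shares of unchanged genes that passed are thus not a rate of false calls. The changed genes lay well above background, so the recovery does not hold for dim genes. Hybridization spike-ins BioB, BioC, BioD and Cre, added at nominal 1.5, 5, 25 and 100 pM, gave slopes of log signal on log concentration of 1.02, 1.07 and 0.971. Their signals over those on the pDC array were 0.766 for CD11b+ cDC and 1.57 for CD8+ cDC over 9 probe sets, and those of the 4 poly-A spike-in probe sets 0.936 and 2.36.

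Alternatives changed 1 choice at a time. Scaling was replaced by centring on the median of probe sets above background on all arrays, by quantile normalization, or by scaling on the hybridization spike-ins. The background was put at the median of all values, at 2 times its level, or left out with log2(signal + 16). A gene was taken as the mean of its probe sets, as probe sets without the suffixes that mark shared or cross-hybridizing sequence, or as passing with every probe set above background. Thresholds were raised to 4-fold for pairs and 8-fold for specific genes, random lists were drawn without matching on signal, and list members at background on both arrays were counted as 0, an alternative chosen after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.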

Results

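Gene expression was measured in 3 subsets of dendritic cells (DC) sorted from the spleens of healthy female C57BL/6 mice aged 6 to 8 weeks. Plasmacytoid DC (pDC) are known for secreting type I interferon. Conventional DC (cDC) present antigen to T cells and were sorted as CD11b+ and CD8+ cells, the subsets also called cDC2 and cDC1. Each subset was hybridised to 1 Affymetrix mouse array of 45101 probe sets, with RNA pooled over 5 to 8 mice. There were no replicate arrays, so no spread between samples could be measured and no p-value or standard error is given. Differences are described by a fixed size rule. A gene was called higher on an array where its intensity, printed here as its signal, was at least 2-fold above that on the other array and above the background level of 111. Where the dimmer array lay at the background level, the fold was taken against that level and is written as at least that size.

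Signals above background were found for 10339 of 18194 genes on the pDC array, 10407 on the CD11b+ cDC array and 10400 on the CD8+ cDC array. Median signals over all probe sets were 97.8, 97.8 and 99.6. Across the 11011 genes above background on any array, Pearson's r of log2 signals was 0.919 between the 2 cDC arrays (Spearman's rho 0.914). It was 0.846 between pDC and CD11b+ cDC (rho 0.843) and 0.832 between pDC and CD8+ cDC (rho 0.827). These values run across genes, which are not independent replicates, and the number of arrays limits their precision. Control probe sets at the 3' end of Actb were 5.71-fold brighter than those at its 5' end on the pDC array, 2.91-fold on the CD11b+ cDC array and 4.08-fold on the CD8+ cDC array. The same ratio for Gapdh was 16.2, 9.68 and 17.6. Scaling the arrays on the hybridization spike-ins in place of the deposited scaling moved the median difference of all genes from near 0. It became -0.32 (log2) for pDC minus CD11b+ cDC, 0.61 for pDC minus CD8+ cDC and -0.98 for CD8+ minus CD11b+ cDC. The spike-ins differed by 0.39, -0.66 and 1.04 (mean log2) in these pairs. Differences are thus relative to the bulk of genes. Medians of gene lists closer to 0 than the spike-in difference can change sign with the scaling.

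The genes encoding the 2 surface proteins that name the cDC sorts followed the sort, which is no finding between these arrays. Itgam, encoding CD11b, gave a signal of 2787 in CD11b+ cDC and lay at background in the other 2 subsets. Cd8a gave 203567 in CD8+ cDC, 32230.5 in pDC and 702 in CD11b+ cDC, and each of its 5 probe sets was brightest in CD8+ cDC. Cd4, the T helper cell coreceptor, gave 37302 in pDC and 14501 in CD11b+ cDC and lay at background in CD8+ cDC at its brighter probe set, while the dimmer one read 153 there. Itgax, encoding CD11c, was 5.60-fold higher in CD11b+ cDC and 3.04-fold higher in CD8+ cDC than in pDC. Bst2, encoding the pDC antigen recognised by antibody PDCA-1, gave 287619 in pDC, 3551 in CD11b+ cDC and 4934 in CD8+ cDC. Ptprc, the gene of CD45 and its B220 isoform, gave 327983, 425232 and 291847. Which proteins defined the pDC sort is not given in the sources used here, so the values of Siglech, Bst2 and Ptprc describe the sort as much as the cells. The marker lists below hold some of these genes. Cd8a is in the CD8+ cDC list, Itgam in the CD11b+ cDC list, and Siglech and Bst2 are in the pDC list.

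**Figure D1:**
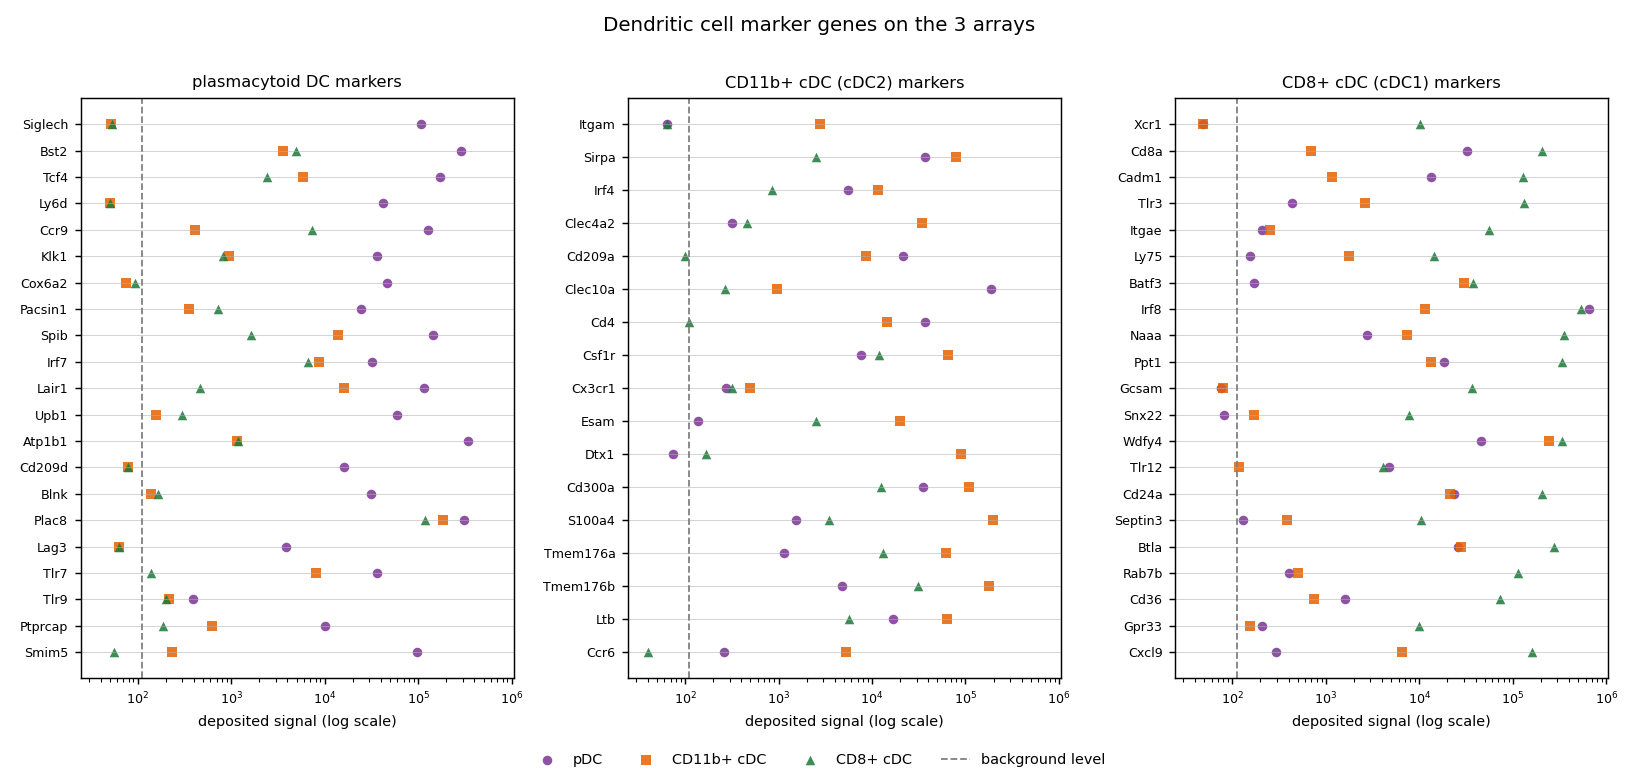
Deposited signal (log scale, horizontal axis) of each measured member of the pDC, CD11b+ cDC and CD8+ cDC marker lists, with 1 point per array (circle for pDC, square for CD11b+ cDC, triangle for CD8+ cDC) and a dashed line at the background level of 111. Most circles in the pDC panel and most triangles in the CD8+ cDC panel lie to the right of the other symbols, while Clec10a, Cd4 and Cd209a in the CD11b+ cDC panel are brightest in pDC.

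The comparison of pDC with CD11b+ cDC asked which genes set plasmacytoid cells apart from the CD11b+ conventional subset. Most plasmacytoid marker genes and many genes of the endoplasmic reticulum (ER) secretory pathway were higher in pDC, while most conventional DC, cell cycle, chemokine and cytokine genes were higher in CD11b+ cDC. Siglech, a sialic acid-binding lectin of pDC, was at least 956-fold higher in pDC, and Tcf4, the transcription factor that specifies pDC, was 29.3-fold higher. In the other direction Batf3 and Zbtb46, transcription factors of the conventional lineage, were 176-fold and 91.3-fold higher in CD11b+ cDC. Of the 10793 genes above background on either array, 1617 were higher in pDC and 1540 were higher in CD11b+ cDC. A difference of at least 10-fold was reached by 299 and 413 of these, and one of at least 100-fold by 53 and 44.

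Among genes with at least 2 measured probe sets, all passing the rule, the pDC array stood highest at Slco4a1, an organic anion transporter (at least 1112-fold), and Havcr1, encoding the phosphatidylserine receptor TIM-1 (at least 732-fold). Next came Dntt, the terminal transferase of antigen receptor rearrangement (at least 511-fold), the receptor tyrosine phosphatase Ptprf (at least 478-fold) and the cytochrome c oxidase subunit Cox6a2 (at least 414-fold). Ccr9, a gut-homing chemokine receptor, was 308-fold higher, the sodium pump subunit Atp1b1 289-fold, Jakmip1 at least 213-fold, Eldr 210.5-fold and the protease gene Ctsl 206-fold. Of such genes, CD11b+ cDC stood highest at Ffar2, a receptor for short-chain fatty acids (838-fold), at Dtx1, a regulator of Notch signalling (at least 804-fold), and at the calcium channel gene Ryr3 (at least 481-fold). Chn2 was at least 273-fold higher, Dna2 233-fold, the efflux pump gene Abcb1a at least 214-fold, Dock5 at least 188-fold, Adam23 at least 152-fold, Hnrnpll 147-fold and Eps8 139-fold. Sizes differed between probe sets of a gene, from 4.30-fold to 804-fold for Dtx1 and from 2.89-fold to 213-fold for Jakmip1. Slco4a1 ranged from 86.8-fold to 1112-fold, Dntt from 7.53-fold to 511-fold and Ptprf from 7.33-fold to 478-fold. Ccr9 ranged from 7.59-fold to 1146-fold and Atp1b1 from 177-fold to 1372-fold. The order of these genes thus depends on the probe set taken.

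Of the 21 measured pDC markers, 19 were higher in pDC and 0 lower, with a median log2 difference of 6.12 (95% binomial interval over members 3.36 to 8.27). Smim5 was 419-fold higher and Ly6d at least 381-fold, whereas Tlr9, a receptor for unmethylated DNA, differed 1.84-fold and Plac8 1.67-fold. Lymphoid-associated genes were higher in pDC for 10 of 15 and lower for 0 (median 1.36), including the B cell adaptor gene Blnk (230.2-fold) and Notch1 (78.8-fold). Of 20 conventional DC markers, 16 were lower in pDC and 0 higher (median -4.29, interval -5.46 to -2.22), led by Nav1 (at least 341-fold). Of 17 CD11b+ cDC markers, 13 were lower and 3 higher (median -3.08), with Esam 148-fold, S100a4 128-fold and Clec4a2 108-fold lower in pDC. The 3 that went against the list's name were Clec10a, a galactose-type lectin (195-fold higher in pDC), Cd4 (2.57-fold) and Cd209a (2.49-fold). With spike-in scaling 1 member was higher in pDC, Cd4 and Cd209a falling below 2-fold. The CD8+ cDC markers went both ways, 5 higher and 7 lower of 19 (median -0.29). Irf8, a transcription factor needed for CD8+ cDC, was 55.9-fold higher in pDC, the profilin receptor gene Tlr12 40.2-fold and Cadm1 11.5-fold, while Cxcl9 was 22.2-fold and Ly75 11.5-fold higher in CD11b+ cDC. Of 39 DC transcription factors, 13 were higher and 12 lower (median 0.00, below 0 with spike-in scaling). Ets1 (24.9-fold) and Ikzf2 (17.1-fold) were on the pDC side, with Id2, an inhibitor of E proteins (43.9-fold), and Myc (at least 25.7-fold) on the other.

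All 29 measured cell cycle genes were lower in pDC (median -4.28, interval -4.88 to -2.82), a median below those of all 10000 random lists matched on signal. Nusap1, a mitotic spindle protein gene, was 69.2-fold lower, Ccnb2 61.5-fold, Bub1 at least 61.2-fold and Ccna2 60.3-fold. The neutrophil markers were lower in pDC as well, 8 of 10 (median -2.24). Chemokine and cytokine genes were lower in pDC for 16 of 18 and higher for 1 (median -2.53). The inflammatory cytokine gene Il1b was 293-fold lower, Ccl5 163-fold, Cxcl16 at least 41.4-fold and Ccl9 25.8-fold, and Ccl4 was 4.31-fold higher. Of 20 costimulatory and coinhibitory genes, 10 were lower and 6 higher (median -1.92). Cd83 was 116-fold, Pdcd1lg2 (PD-L2) at least 28.1-fold, Cd80 24.6-fold and Cd40 20.7-fold higher in CD11b+ cDC. Lag3 was at least 34.5-fold, the tryptophan-degrading enzyme gene Ido1 at least 17.6-fold and Cd200 9.27-fold higher in pDC. Chemokine and trafficking receptors split evenly, 6 higher and 6 lower of 18 (median -0.15). Cxcr3 (51.8-fold), S1pr4 (22.9-fold) and Ccr2 (13-fold) were higher in pDC, and Ccrl2 (61.9-fold), the lymph node homing receptor gene Ccr7 (36.1-fold) and Ccr6 (20.2-fold) in CD11b+ cDC. Of 23 C-type lectin, Fc and uptake receptor genes, 7 were higher and 11 lower (median -0.97), with Cd209d (at least 145-fold) and Cd209e (at least 11.3-fold) on the pDC side and the beta-glucan receptor gene Clec7a (55.5-fold) and Clec4a3 (26.1-fold) on the other.

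Genes of the ER secretory pathway and unfolded protein response were higher in pDC for 18 of 33 and lower for 0 (median 1.09, interval 0.66 to 1.5), above all 10000 matched random lists, and for 12 with spike-in scaling. Edem2 was 4.75-fold, the protein disulfide isomerase gene Pdia4 4.59-fold, the chaperone gene Dnajb9 4.46-fold and Creld2 3.72-fold higher. Of 8 plasma cell markers, 4 were higher and 2 lower (median 0.92). The immunoglobulin folding cofactor gene Mzb1 was 192-fold and Sdc1 at least 30.2-fold higher in pDC, and Prdm1 was 2.72-fold and Irf4 2.10-fold lower. Class II presentation genes were lower in pDC for 6 of 15, or 10 with spike-in scaling, and higher for 0 (median -0.78), led by H2-Ob (18.1-fold), the class II transactivator gene Ciita (4.66-fold) and H2-Oa (2.98-fold). Of 17 class I presentation genes, 1 was higher, the peptide loading factor gene Tapbp (2.19-fold), and 0 were lower; the median of 0.26 turned to -0.12 with the arrays scaled on hybridization spike-ins. Lysosomal genes were higher for 7 of 22 and lower for 2 (median 0.42), with Ctsb 3.0-fold and Npc2 2.87-fold higher and Naaa 2.70-fold and Tfeb 2.12-fold lower in pDC.

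Toll-like receptors and adaptors were higher in pDC for 3 of 22 and lower for 7 (median -0.22). The RNA receptor gene Tlr7 was 4.50-fold and Irf7, the interferon regulatory factor of the pDC response, 3.69-fold higher. Tlr1 was at least 457-fold, Tlr13 148-fold, the flagellin receptor gene Tlr5 at least 6.36-fold and Tlr6 6.18-fold higher in CD11b+ cDC. Of 15 genes of cytosolic nucleic acid sensing, 6 were lower in pDC and 1 higher (median -0.12). Ddx58, encoding the RNA sensor RIG-I, was 53.6-fold, the DNA sensor gene Cgas 11.9-fold and Zbp1 4.12-fold lower, and the kinase gene Ikbke was 5.40-fold higher. Interferon-stimulated genes split, 5 higher and 7 lower of 26 (median -0.20), with Oasl1 (4.43-fold) and Trim30a (3.67-fold) higher in pDC and Rtp4 (65.0-fold), Oas2 (18.9-fold), Ifit1 (16.2-fold) and Ddx60 (15.9-fold) higher in CD11b+ cDC.

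Actin and motility genes were lower in pDC for 12 of 28 and higher for 3 (median -0.91). Anxa1 was 55.5-fold, the filopodia bundling gene Fscn1 30.2-fold and Myo1f 8.61-fold lower, while Ahnak (94.3-fold), Capg (66.8-fold) and Lgals1 (19.7-fold) were higher. Immediate early genes, which also respond to cell isolation, were lower in pDC for 10 of 18 and higher for 2 (median -1.70). Atf3 was 42.0-fold, Egr2 23.9-fold, Nr4a1 22.0-fold and Ier3 19.6-fold lower, and Fosb was 2.56-fold and Jun 2.38-fold higher. None of 25 oxidative phosphorylation genes reached 2-fold (median -0.04), though 2 were lower in pDC with spike-in scaling. Of 14 housekeeping genes, the transferrin receptor gene Tfrc was higher in pDC (2.63-fold) and Gapdh (2.18-fold) and Hprt (2.02-fold) were lower (median -0.23). The split of calls depended on the scaling: pDC held 51.2% of the calls with the deposited values and 33.4% with the arrays scaled on the hybridization spike-ins.

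**Figure D2:**
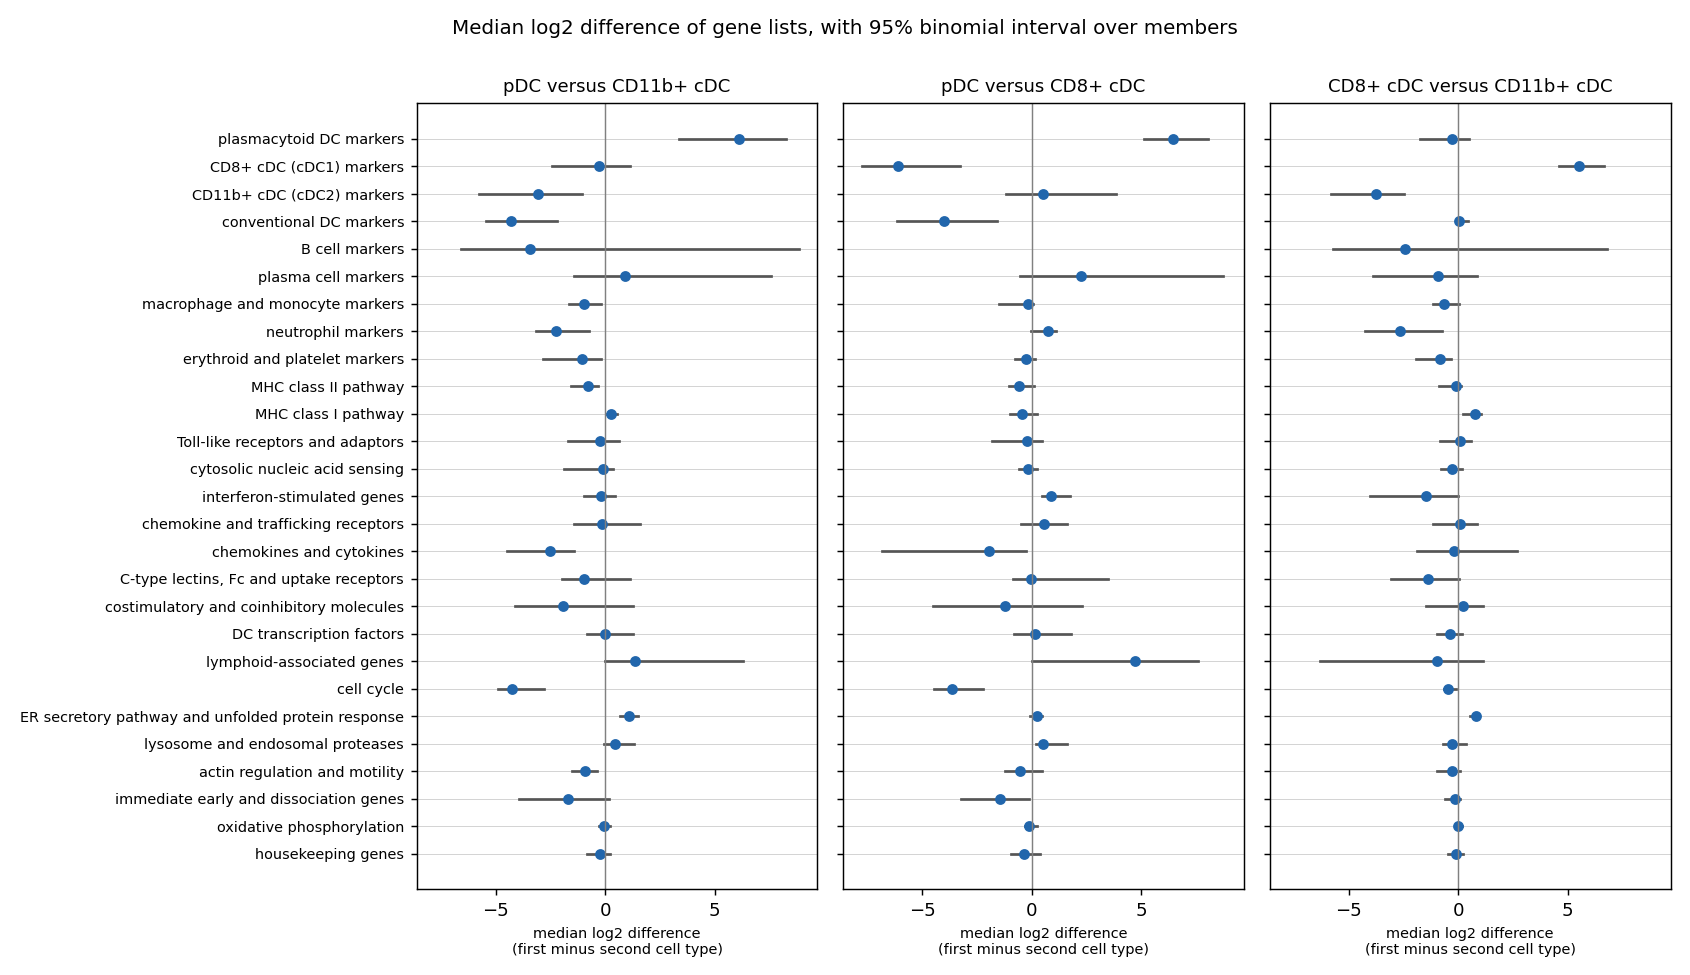
Median log2 difference of each gene list with at least 6 measured members (point) and its 95% binomial interval over members (bar), in 3 panels for pDC versus CD11b+ cDC, pDC versus CD8+ cDC and CD8+ cDC versus CD11b+ cDC; values right of the vertical line at 0 are higher in the first cell type of the panel. The cell cycle list lies at -4.28 and -3.67 in the pDC panels, and oxidative phosphorylation lies between -0.13 and -0.01 in all 3, values that move with all genes under spike-in scaling.

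The comparison of pDC with CD8+ cDC asked the same of the CD8+ conventional subset. Most plasmacytoid and lymphoid-associated genes were higher in pDC, and most CD8+ cDC markers, conventional DC markers, cell cycle genes and chemokine and cytokine genes were higher in CD8+ cDC. Clec10a was 691-fold higher in pDC and Cd4 at least 336-fold. Cxcl9, an interferon-gamma-induced chemokine gene, was 546-fold higher in CD8+ cDC and Tlr3, a receptor for double-stranded RNA, 305-fold. Of 10823 genes above background on either array, 1728 were higher in pDC and 1603 in CD8+ cDC. At least 10-fold was reached by 324 and 418, and at least 100-fold by 63 and 62.

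Among genes with at least 2 measured probe sets that all passed, pDC stood highest at Slco4a1 (832-fold), Havcr1 (at least 732-fold), Dntt (at least 511-fold), Ptprf (425-fold), the lysosomal membrane transporter gene Slc49a4 (418-fold) and Cox6a2 (at least 414-fold). Lrp8, a receptor for reelin and apolipoprotein E, was 380.4-fold higher, the phospholipid transfer protein gene Pltp 363-fold and the kinase gene Stk26 at least 306-fold. Of such genes, CD8+ cDC stood highest at Cxcl9 and at Gcsam (at least 332-fold), followed by Sema4f (at least 323-fold), Cxcl16 (at least 318-fold) and Tlr3. The small GTPase gene Rab7b was 279-fold higher, Dock5 at least 277-fold, Rasgrp3 269.7-fold, Itgae, encoding the integrin CD103, 265-fold, and Olfm1 241-fold. Probe sets of Slc49a4 ranged from 4.07-fold to 418-fold, those of Lrp8 from 3.73-fold to 380.4-fold and those of Rab7b from 11.6-fold to 279-fold.

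Smim5 was at least 868-fold higher in pDC. Of 21 pDC markers, 20 were higher in pDC, or 21 with spike-in scaling, and 0 lower (median 6.46, interval 5.11 to 8.03), with Tlr9 the exception at 1.94-fold on the deposited scale. CD8+ cDC markers mirrored this, 19 of 21 lower in pDC and 0 higher (median -6.11, interval -7.78 to -3.27); the other 2, Irf8 and Tlr12, differed 1.21-fold and 1.16-fold toward pDC. Of 20 conventional DC markers, 16 were lower, or 14 with spike-in scaling, and 0 higher (median -4.02, interval -6.17 to -1.60). Among the lower ones were Batf3 (219-fold), Adam23 (at least 172-fold), Zbtb46 (148-fold) and Nav1 (at least 132-fold). CD11b+ cDC markers were more often higher in pDC, 8 higher and 4 lower of 16 (median 0.49, interval -1.18 to 3.86), with Cd209a at least 194-fold and Sirpa 14.5-fold higher and Esam 18.5-fold and Tmem176a 11.3-fold lower. Lymphoid-associated genes were higher for 11 of 15 (median 4.73), among them Blnk (193-fold), and Cd8a was the 1 that was lower. Transcription factors were higher for 17 of 39 and lower for 12 (median 0.14). Ets1 (146-fold), Spib (88.2-fold), Tcf4 (71.4-fold) and Zeb2 (53.8-fold) were on the pDC side and Id2 (71.8-fold) and Myc (at least 17.3-fold) on the CD8+ cDC side.

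Cell cycle genes were lower in pDC for 26 of 29 and higher for 0 (median -3.67, interval -4.44 to -2.23), with Ccnb2 71.6-fold, Bub1 at least 57.5-fold, Cdk1 at least 47.1-fold and Tpx2 42.2-fold lower. Of 18 chemokine and cytokine genes, 13 were lower and 3 higher (median -1.94). Ccl22 was at least 142-fold and Il1b 139.8-fold higher in CD8+ cDC, while Ccl4 was 16.1-fold, Ccl3 10.6-fold and the lymphotoxin gene Ltb 2.96-fold higher in pDC. Costimulatory and coinhibitory genes were lower for 11 of 19 and higher for 6 (median -1.23), with Cd83 (176-fold), Cd86 (107-fold) and Havcr2 (37.4-fold) higher in CD8+ cDC and Lag3 (at least 34.5-fold), Lgals9 (7.83-fold) and Cd200r1 (6.30-fold) in pDC. Chemokine and trafficking receptors were higher in pDC for 7 of 18 and lower for 4 (median 0.58). Ccr2 was 25.4-fold, S1pr4 18.7-fold and the oxysterol receptor gene Gpr183 10.2-fold higher in pDC, and Xcr1, the chemokine receptor of cross-presenting DC, was at least 91.5-fold and Ccr7 65.7-fold higher in CD8+ cDC. Of 22 lectin, Fc and uptake receptor genes, 7 were higher and 5 lower (median -0.04, above 0 with spike-in scaling), with Ly75, encoding the endocytic receptor DEC-205, 93.0-fold and the scavenger receptor gene Cd36 46.0-fold higher in CD8+ cDC.

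Interferon-stimulated genes were higher in pDC for 12 of 26 and lower for 1 (median 0.89, interval 0.46 to 1.74), above all 10000 matched random lists, and for 17 of 25 and 0 with spike-in scaling. Oasl2 was 27.1-fold, Ifi27l2a 21.6-fold and Cmpk2 8.31-fold higher, and Mx1 was 2.80-fold higher in CD8+ cDC. Toll-like receptors and adaptors were higher for 3 of 21 and lower for 7 (median -0.23, above 0 with spike-in scaling). Tlr7 was 261-fold and the endolysosomal transporter gene Slc15a4 7.52-fold higher in pDC, and Tlr13 was 151-fold, Tlr1 at least 34.2-fold and Tlr4 3.99-fold higher in CD8+ cDC. Cytosolic sensing genes went 2 higher and 2 lower of 15 (median -0.16, above 0 with spike-in scaling). Ikbke was 6.59-fold and the adaptor gene Sting1 5.04-fold higher in pDC, and Cgas was 11.9-fold and Zbp1 2.41-fold lower. Class I presentation genes were lower in pDC for 4 of 17, including Tap1 (2.98-fold) and its transactivator gene Nlrc5 (2.18-fold), and higher for 0 (median -0.43), and went 3 higher and 0 lower with spike-in scaling, the median then above 0. Class II genes were lower for 4 of 15 and higher for 1 (median -0.61, above 0 with spike-in scaling), with H2-Ob 12.3-fold and the ubiquitin ligase gene Marchf1 5.78-fold higher in CD8+ cDC.

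Lysosomal genes were higher in pDC for 9 of 22, or 15 with spike-in scaling, and lower for 3 (median 0.50, interval 0.21 to 1.61). The proteases Ctsl (269.9-fold), Ctsd (7.88-fold) and Ctsa (5.52-fold) were on the pDC side, and Naaa (129-fold), Ppt1 (18.7-fold) and the protease inhibitor gene Cst3 (5.70-fold) on the other. ER secretory genes were higher for 5 of 33, or 13 with spike-in scaling, and lower for 1 (median 0.25), with Edem2 3.47-fold, Spcs2 2.52-fold and the transcription factor gene Xbp1 2.52-fold higher and Sdf2l1 4.34-fold lower. Plasma cell markers were higher for 6 of 8 and lower for 0 (median 2.25), with Mzb1 at least 429-fold and Jchain 8.22-fold higher. Actin and motility genes went 6 higher and 11 lower of 28 (median -0.54), or 9 higher and 7 lower with spike-in scaling, the median then above 0, with Capg (at least 222-fold), Lgals1 (53.7-fold) and Ahnak (16.9-fold) higher and Anxa1 (102-fold), Lgals3 (38.8-fold) and Fscn1 (26.8-fold) lower. Immediate early genes were lower for 9 of 18 and higher for 2 (median -1.45), with Atf3 33.1-fold, Egr2 24.4-fold and Ier3 20.4-fold lower in pDC and Jun 4.70-fold higher. None of 25 oxidative phosphorylation genes reached 2-fold (median -0.13), though 6 were higher in pDC with spike-in scaling and the median was then above 0, and of 14 housekeeping genes Tfrc was 11.6-fold higher while Gusb was 10.1-fold and Pgk1 3.21-fold lower (median -0.37, above 0 with spike-in scaling). With the arrays scaled on the hybridization spike-ins, 3433 genes were higher in pDC and 967 in CD8+ cDC, and the share of calls held by pDC moved from 51.9% to 78.0%.

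The comparison of CD8+ with CD11b+ cDC asked how the 2 conventional subsets differ. Most CD8+ cDC markers were higher in CD8+ cDC, and most CD11b+ cDC markers and interferon-stimulated genes were higher in CD11b+ cDC. Itgae was 217-fold higher in CD8+ cDC, Irf8 46.3-fold and the cytokine subunit gene Il12b 44.5-fold. Dtx1 was 527-fold higher in CD11b+ cDC, Rtp4 96.9-fold and Irf4, a transcription factor of CD11b+ cDC, 13.7-fold. Of 10709 genes above background on either array, 1054 were higher in CD8+ cDC and 1099 in CD11b+ cDC. Differences of at least 10-fold numbered 168 and 178, and those of at least 100-fold 17 and 6.

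Among genes with at least 2 measured probe sets that all passed, CD8+ cDC stood highest at Gcsam (at least 332-fold), the sort gene Cd8a (290.0-fold), Rab7b (224-fold) and Itgae. The Wnt receptor gene Fzd1 was 153-fold higher, the secreted Wnt modulator gene Dkk3 at least 142-fold, Fcrla 111-fold, the adhesion gene Cadm1 110.3-fold, Cd36 99.2-fold and Sh3pxd2b 98.7-fold. Of such genes, CD11b+ cDC stood highest at Dtx1, Ryr3 (431-fold), Cd4 (at least 130.4-fold), Rtp4, Mmp9, encoding gelatinase B (at least 79.5-fold), and Ddx58 (62.6-fold). Tlr7 was 58.0-fold higher, Abcb1a 55.6-fold, the transporter chaperone gene Emb 54.2-fold and Cd22, an inhibitory sialic acid receptor of B cells, 52.6-fold. Probe sets of Fzd1 ranged from 3.77-fold to 153-fold, those of Sh3pxd2b from 3.73-fold to 98.7-fold, and those of Ddx58 from 2.29-fold to 62.6-fold.

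Of 21 CD8+ cDC markers, 19 were higher in CD8+ cDC and 0 lower (median 5.53, interval 4.62 to 6.63); the other 2, Wdfy4 and Batf3, differed 1.37-fold and 1.25-fold toward CD8+ cDC, and both turned toward CD11b+ cDC with spike-in scaling. Of 17 CD11b+ cDC markers, 16 were lower in CD8+ cDC, or 17 with spike-in scaling, and 0 higher (median -3.78, interval -5.81 to -2.49). Cd209a was at least 77.8-fold and Clec4a2 75.4-fold lower, with Cx3cr1 the exception at 1.55-fold on the deposited scale. Conventional DC markers went 1 higher and 3 lower of 20 (median 0.05), and 1 higher and 10 lower with spike-in scaling (median -0.99). Cd86 was 5.46-fold higher in CD8+ cDC and Relb 3.04-fold, Nav1 2.58-fold and the stem cell factor receptor gene Kit 2.35-fold higher in CD11b+ cDC. The pDC markers were lower in CD8+ cDC for 6 of 16 and higher for 2 (median -0.29), and for 10 and 1 with spike-in scaling (median -1.15). Tlr7, Lair1 (35.1-fold), Spib (8.60-fold) and Ptprcap (3.37-fold) were higher in CD11b+ cDC and Ccr9 (17.9-fold) in CD8+ cDC. Transcription factors were lower in CD8+ cDC for 12 of 39 and higher for 3 (median -0.37), and for 22 of 38 and 2 with spike-in scaling (median -1.31), with Zeb2 9.43-fold lower and Mycl 6.95-fold and Nfil3 3.80-fold higher. Of 11 lymphoid-associated genes, 5 were lower and 2 higher (median -0.98), with Cd7 79.2-fold and Foxp1 7.5-fold lower.

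Interferon-stimulated genes were lower in CD8+ cDC for 15 of 26 and higher for 4 (median -1.46, interval -4.05 to -0.01), below all 10000 matched random lists, and for 20 and 0 with spike-in scaling. Oasl2 was 41.3-fold, Oas1a 31.0-fold and Ddx60 at least 26.9-fold lower, and Mx1 was 3.81-fold and Oasl1 2.87-fold higher. Of 15 cytosolic sensing genes, 3 were lower and 1 higher (median -0.29), or 10 lower and 0 higher with spike-in scaling (median -1.33), with Sting1 3.97-fold and Ifih1, encoding the RNA sensor MDA5, 3.86-fold lower. Toll-like receptors and adaptors went 3 higher and 5 lower of 22 (median 0.07), and 2 higher and 10 lower with spike-in scaling (median -0.94). Tlr3 was 50.5-fold and Tlr12 34.7-fold higher in CD8+ cDC, and Tlr1 was 13.3-fold, Tlr5 at least 6.36-fold and Slc15a4 4.90-fold higher in CD11b+ cDC. C-type lectin, Fc and uptake receptor genes were lower for 12 of 19 and higher for 3 (median -1.40), with Clec4a3 20.1-fold and the Fc receptor gamma chain gene Fcer1g 17.3-fold lower and Ly75 8.10-fold and Fcgr2b 3.90-fold higher. Chemokines and cytokines went 6 higher and 8 lower of 19 (median -0.21). Cxcl9 was 24.5-fold, Ccl22 18.2-fold and Cxcl16 7.69-fold higher in CD8+ cDC, and Ccl3 was 51.8-fold, Ccl9 21.5-fold, Ltb 11.1-fold and the interleukin-1 receptor antagonist gene Il1rn at least 6.83-fold higher in CD11b+ cDC. Receptors of chemokines and trafficking went 4 higher and 5 lower of 19 (median 0.06, below 0 with spike-in scaling), with Xcr1 at least 91.5-fold and Cxcr3 25.6-fold higher in CD8+ cDC and Ccr6 at least 47.1-fold, Gpr183 19.9-fold and Ccrl2 15.5-fold higher in CD11b+ cDC. Of 19 costimulatory and coinhibitory genes, 5 were higher and 7 lower (median 0.22, below 0 with spike-in scaling), with Btla 9.91-fold, Ido1 at least 8.33-fold and Pvr 5.96-fold higher and Fasl at least 15.0-fold, Pdcd1lg2 12-fold, Lgals9 7.62-fold and Cd274 (PD-L1) 5.27-fold lower.

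Class I presentation genes were higher in CD8+ cDC for 5 of 17 and lower for 0, and the median of 0.76 (interval 0.20 to 1.05) turned to -0.28 with spike-in scaling, with 0 higher and 3 lower. Nlrc5 was 3.84-fold, Erap1, which trims peptides in the ER, 2.84-fold (with a second probe set at -0.69 log2), Tapbpl 2.40-fold and Tap1 2.39-fold higher. ER secretory genes were higher for 9 of 33 and lower for 0, and their median of 0.80 (interval 0.52 to 0.94) turned to -0.24 with spike-in scaling, with 1 higher and 3 lower. Pdia4 was 4.13-fold, Creld2 4.01-fold, Sdf2l1 3.91-fold and Ero1b 2.88-fold higher. Class II genes went 2 higher and 2 lower of 15 (median -0.09), or 0 higher and 10 lower with spike-in scaling (median -1.13, interval -1.93 to -0.90), with Marchf1 2.34-fold higher and H2-DMb2 4.16-fold lower. Lysosomal genes went 5 higher and 4 lower of 22 (median -0.31), and 3 higher and 14 lower with spike-in scaling (median -1.35). The lipid amidase gene Naaa was 47.7-fold, the thioesterase gene Ppt1 25.6-fold and Cst3 4.43-fold higher in CD8+ cDC, and the proteases Ctsd (4.78-fold) and Ctsa (4.66-fold) were higher in CD11b+ cDC. Actin and motility genes were lower in CD8+ cDC for 8 of 28, or 18 with spike-in scaling, and higher for 2 (median -0.28), with S100a4 56.3-fold, S100a6 13.3-fold and Rac2 4.18-fold lower and Lgals3 9.19-fold and Ahnak 5.59-fold higher. Of 29 cell cycle genes, 6 were lower in CD8+ cDC and 0 higher (median -0.47, interval -0.66 to -0.09), and 25 were lower with spike-in scaling (median -1.51), with Nusap1 2.79-fold and Kif11 2.66-fold lower. Immediate early genes were lower for 2 of 18, Nr4a1 (2.35-fold) and Zfp36 (2.13-fold), and higher for 0 (median -0.16), and lower for 12 with spike-in scaling. None of 25 oxidative phosphorylation genes reached 2-fold (median -0.01), though 13 were lower in CD8+ cDC with spike-in scaling. Of 14 housekeeping genes Gusb, a lysosomal glucuronidase gene, was 15.1-fold and Pgk1 2.97-fold higher and Tfrc 4.42-fold lower (median -0.10), and 9 were lower with spike-in scaling. With spike-in scaling 387 genes were higher in CD8+ cDC and 5205 in CD11b+ cDC, and the share of calls held by CD8+ cDC moved from 49.0% to 6.92%.

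At 4-fold over both other subsets, 470 genes were specific to pDC, 222 to CD11b+ cDC and 267 to CD8+ cDC, of 11011 genes above background on any array. Beyond the genes above, the pDC set included Ablim1 (at least 131-fold over the brighter of the other 2), Lynx1 (131-fold) and the fatty acid desaturase family gene Fads3 (at least 126-fold). The CD11b+ cDC set included the cytochrome P450 gene Cyp4f16 (26.1-fold), the cytokine receptor gene Il31ra (25.9-fold), the sialyltransferase gene St8sia6 (25-fold) and 2900052N01Rik (at least 48.6-fold). The CD8+ cDC set included Fam149a (at least 91.0-fold), the lipid phosphatase gene Plpp1 (81.3-fold), the hexokinase gene Hk3 (50.2-fold), the protease inhibitor gene Serpinb8 (at least 48.6-fold) and Farp2 (48.0-fold).

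Markers of other spleen cells showed what else the sorts could hold, after the bead depletion of T and B cells. Of the neutrophil markers, 8 of 10 were lower in CD8+ than in CD11b+ cDC (median -2.65, interval -4.28 to -0.76), the same count as in pDC, while 3 of 9 were higher in pDC than in CD8+ cDC (median 0.74). The granule protein genes Mmp9, Ngp (19.4-fold) and Camp (7.76-fold) and the calprotectin gene S100a8 (18.2-fold) were higher in CD11b+ than in CD8+ cDC, with S100a8 at a signal of 4393 in CD11b+ cDC, 489.8 in pDC and 242 in CD8+ cDC. Macrophage and monocyte markers were lower in pDC than in CD11b+ cDC for 8 of 17 and higher for 2 (median -0.97), with Adgre1, encoding F4/80 (26.7-fold), and the lysozyme gene Lyz2 (25.8-fold) higher in CD11b+ cDC. Against CD8+ cDC they were lower in pDC for 5 and higher for 3 (median -0.16, above 0 with spike-in scaling), and CD8+ cDC were lower than CD11b+ cDC for 7, or 12 with spike-in scaling, and higher for 1 (median -0.63), the metal transporter gene Slc11a1 (13-fold). Erythroid and platelet markers were lower in pDC than in CD11b+ cDC for 5 of 9 (median -1.08), with the platelet chemokine genes Pf4 9.10-fold and Ppbp 7.23-fold higher in CD11b+ cDC. They were lower for 1 against CD8+ cDC (median -0.26, above 0 with spike-in scaling), and lower in CD8+ than CD11b+ cDC for 3 (median -0.82), or 8 with spike-in scaling.

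Lymphocyte markers went in different directions. Of 6 measured B cell markers, Cd22 (95.9-fold), Ms4a1, encoding CD20 (49.5-fold), Bank1 (25.9-fold) and Cr2 (at least 4.57-fold) were higher in CD11b+ cDC than in pDC, and Fcrla (465-fold) and Cd79b (2.51-fold) were higher in pDC (median -3.44). Against CD8+ cDC, 2 of 5 were higher and 2 lower in pDC (median -0.87), and CD8+ cDC were higher than CD11b+ cDC at 1 of 6 and lower at 4 (median -2.42). Cd79a, Pax5 and Ebf1, the genes of B cell identity, lay at background on all 3 arrays. Plasma cell markers were lower in CD8+ than in CD11b+ cDC for 3 of 7 and higher for 0 (median -0.92), led by Jchain (14.7-fold). Of 4 measured T cell markers, Cd28 (at least 43.4-fold), Il7r (28.1-fold) and Lat (2.36-fold) were higher and Cd5 (8.25-fold) lower in pDC than in CD11b+ cDC (median 3.03), and Cd3e, Cd3d and Cd3g lay at background throughout. Il7r (55.7-fold) and Cd28 (at least 43.4-fold) were higher in pDC than in CD8+ cDC (median 3.09), and Cd5 was 6.55-fold lower in CD8+ than in CD11b+ cDC (median -0.98). Of 5 measured NK cell markers 2 were lower in pDC than in CD11b+ cDC, Klrk1 (2.44-fold) and Gzma (2.06-fold), and 0 higher (median -0.09). Klrd1 was 21.8-fold higher in pDC than in CD8+ cDC and Klrk1 6.31-fold lower (median -0.02), and CD8+ cDC were 2.58-fold higher than CD11b+ cDC at Klrk1, 18.9-fold lower at Klrd1 and 2.07-fold lower at Gzma (median -0.09).

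**Figure D3:**
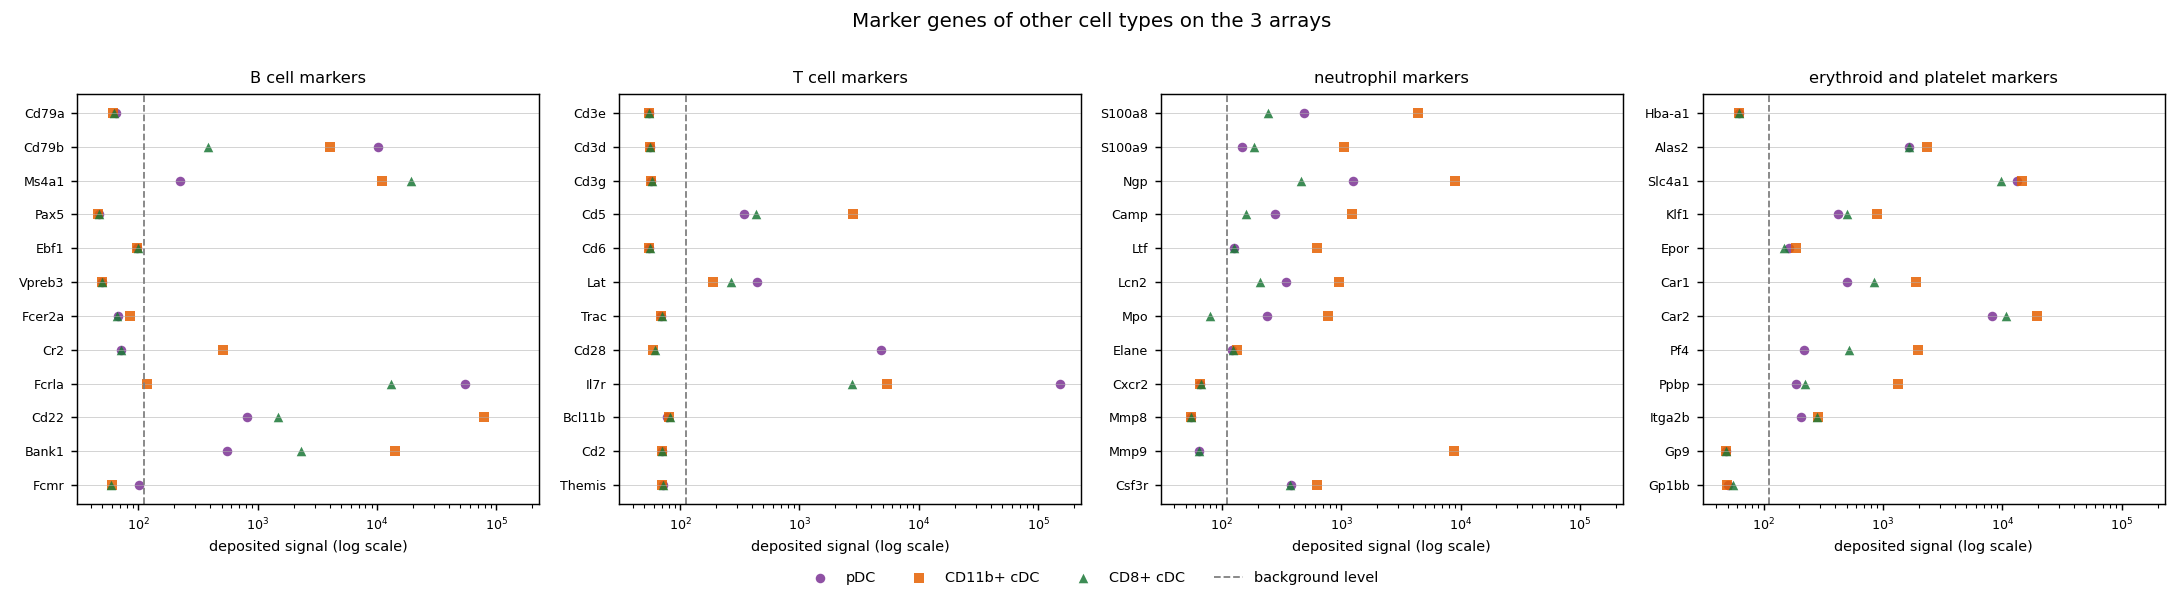
Deposited signal (log scale, horizontal axis) of B cell, T cell, neutrophil, and erythroid and platelet marker genes, with 1 point per array (circle for pDC, square for CD11b+ cDC, triangle for CD8+ cDC) and a dashed line at the background level of 111. S100a8, Ngp and Mmp9 are brightest in CD11b+ cDC, with Mmp9 at 8833 there, while Cd79a, Pax5, Cd3e and Cd3d lie left of the line on all 3 arrays.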

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

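The tests of explanations in this part were all chosen after the results were seen. Probe sets listed with no gene or with several genes entered no comparison above, and some of them carried strong differences between the arrays. At least 4-fold over both other cell types, 125 such probe sets were higher in pDC, 37 in CD11b+ cDC and 42 in CD8+ cDC. In pDC the leading one was 1445710_x_at with at least 715-fold (signal 79527.9 against 49.8 in CD11b+ cDC and 50.4 in CD8+ cDC, both at background), and in CD11b+ cDC 1448025_at at 153-fold (162570.0 against 290.0 and 1064); both are listed with several genes. In CD8+ cDC it was 1430419_at, listed with no gene, at 414-fold (100594 against 243 in pDC and 197 in CD11b+ cDC).

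Cell cycle genes were lower in pDC than in both cDC subsets. With the arrays scaled on the hybridization spike-ins the median nearer to 0 of the 2 was -3.13 (log2), for pDC minus CD8+ cDC. Against CD8+ cDC, the shift from the deposited to the spike-in scaling is thus too small to account for the lower cell cycle genes. Against CD11b+ cDC that scaling shifted all genes toward CD11b+ cDC. It could only enlarge the difference there, so it does not test array scaling in that pair. Cycling cells of another type could also raise these genes in the cDC sorts. Of B cell genes, Cd79a, Pax5 and Ebf1 lay at background on all 3 arrays, while Cd79b and Ms4a1 lay above it. Over the lists of other cell types, the highest share of members on the array that were 2-fold higher than in pDC was 29.4% in CD8+ cDC (macrophage and monocyte markers) and 66.7% in CD11b+ cDC (neutrophil markers), which leaves such cells open, and they cannot be told apart from cycling cDC. A lower share of dividing cells in pDC than in both cDC subsets stays a hypothesis, since tests and pattern come from the same 3 arrays.

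Neutrophil marker genes were higher in CD11b+ cDC than in both other subsets. The cells were sorted by flow cytometry, with gates not described here. With spike-in scaling the smaller of the 2 medians was 2.52 (log2). That scaling shifted all genes toward CD11b+ cDC against both other arrays. It could only enlarge the difference, so it does not test array scaling as a source. Of 10 measured markers, 8 were at least 2-fold higher than in each of the other arrays. Neutrophil-lineage cells or their RNA in that sort could give such a count. The count restates the pattern, so it is no test of them. S100a8, among the most abundant transcripts of neutrophils, reached 4393, S100a9 1065, Ngp 8912 and Lcn2 955, while Cxcr2 and Mmp8 lay at background. Expression of these genes by CD11b+ cDC themselves was not tested and stays open.

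Cd22, Bank1 and Ms4a1, known as B cell genes, were higher in CD11b+ cDC than in pDC, and Ms4a1 and Bank1 also in CD8+ cDC, after bead depletion of B cells. B cells in the CD11b+ cDC sort could carry these transcripts. Of 12 B cell markers with probe sets, 6 lay above background in CD11b+ cDC, Cd79b (4026) among them. Ighm, given below, was also above background there. The other 6 markers, Cd79a, Pax5, Ebf1, Vpreb3, Fcer2a and Fcmr, lay at background in every probe set. They were picked after their values were seen, so their count is no independent test of B cells. A single misreading probe set is not the source of the Cd22 signal, since 2 probe sets were higher there than in both other arrays, by 52.6-fold and at least 28.5-fold. Expression of Cd22 by CD11b+ cDC remains a hypothesis. Both probe sets of Ms4a1 were brighter in CD8+ cDC (19147 and 4002) than in CD11b+ cDC (11047 and 2568), and Bank1 rests on 1 probe set.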

How the results depend on the processing

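Counting list members at background on both arrays as 0 was chosen after the data were seen; the other alternatives were not. No paired analysis was possible because each cell type has 1 array, so there are no pairs of replicates, and no replicate could be left out. Centring on the median and quantile normalization moved 0 of the 9 gene counts by over 1.5 times. They could hardly do so, since the deposited distributions were already nearly alike. Scaling on the hybridization spike-ins moved 6 of the 9. It gave 3433 genes higher in pDC and 967 higher in CD8+ cDC in that pair, 387 higher in CD8+ cDC and 5205 higher in CD11b+ cDC in the other, and 423 genes specific to CD11b+ cDC and 130 specific to CD8+ cDC. With it, list medians for CD8+ minus CD11b+ cDC moved to 4.49 for CD8+ cDC markers, -0.99 for conventional DC markers and -1.51 for cell cycle genes, and reversed to -0.28 for class I presentation and -0.24 for the ER secretory pathway; for pDC minus CD11b+ cDC, class I presentation reversed to -0.12. These follow the shift of all genes that the scaling makes, and whether spike-ins or the deposited scale is nearer the truth was not tested. By construction stricter thresholds gave fewer genes. At 4-fold, 647 were higher in pDC and 778 in CD11b+ cDC, 743 in pDC and 819 in CD8+ cDC, and 403 in CD8+ cDC and 423 in CD11b+ cDC. At 8-fold, 257 were specific to pDC, 120 to CD11b+ cDC and 126 to CD8+ cDC. Without probe sets that carry a suffix, a second probe set called 60.1%, 61.3% and 56.2% of called genes, in the order pDC and CD11b+ cDC, pDC and CD8+ cDC, and the cDC pair; the cause was not tested. Of 270 recomputed list medians whose interval excluded 0, 2 moved outside it and 3 changed sign, those above. Of 450 whose interval held 0, 17 moved outside it and 21 changed sign, 14 of these with spike-in scaling. Of 27 from 5-member lists, which have no interval, 7 moved by at least 0.5 (log2) and 1 changed sign. Of named gene differences recomputed, 3592 stayed within the spread between probe sets and 398 moved beyond it. Much of this split was fixed by the alternatives. Centring on the median and quantile normalization moved 0 of 506 each. Spike-in scaling shifts genes above background alike, by the size of the mean spike-in difference. That was 0.39, -0.66 and 1.04 (log2) in the same order of pairs, against spreads of 0.86, 0.89 and 0.74. Such genes could thus move beyond the spread only in the cDC pair. None changed sign among differences of 2-fold or more, which such shifts could hardly cause. Of these differences, the spike-in scaling brought 29 of 418 below 2-fold and the mean of all probe sets 19. Doubling the background level moved 89 of 506 gene differences, against 137 with spike-in scaling and 134 with the mean of all probe sets, and folds against an array at background are bounds that depend on that level.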

Other observations

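No tests of explanations are reported in this part, and its genes were chosen after their values were seen. Some genes divided the 3 subsets along another line than pDC against cDC. Shared by pDC and CD8+ cDC and low in CD11b+ cDC were Irf8 (signals 646349, 534491 and 11554 in the order pDC, CD8+ cDC, CD11b+ cDC), the profilin receptor gene Tlr12 (4685, 4045 and 117), the chemokine receptor gene Cxcr3 (54069.9, 26748 and 1045) and the B cell Fc receptor-like gene Fcrla (54639, 13003 and 118). Shared by pDC and CD11b+ cDC and low in CD8+ cDC were the NK cell lectin gene Klrd1 (96243, 83389 and 4413 in the order pDC, CD11b+ cDC, CD8+ cDC), Cd7 (36986, 55320.1 and 698), Cd79b, a subunit of the B cell receptor (10103, 4026 and 381), and Foxp1, a transcription factor of B cell development (13786, 6244 and 833). Ighm, the gene of the IgM heavy chain, gave 171513, 142572 and 50809 on the pDC, CD11b+ cDC and CD8+ cDC arrays, while Cd79a lay at background on all 3.

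Lymphoid-associated genes did not move as a block. In pDC, Dntt reached 56845 and Rag1 640.2, both at background in the cDC subsets, whereas Rag2 and Igll1 lay at background on all 3 arrays and Pou2af1 close to it (136, 138 and 156). Among transcription factors, Bcl11a, needed for pDC development, was 2.39-fold higher in pDC than in CD11b+ cDC and 4.34-fold higher than in CD8+ cDC, and the growth factor receptor gene Csf1r, a CD11b+ cDC marker, was 8.47-fold higher in CD11b+ cDC than in pDC and 5.51-fold higher than in CD8+ cDC. The cytokine receptor gene Flt3, which DC development requires, differed less than 2-fold in each pair (42851, 56499 and 78033), and Notch2 gave the same value in pDC and CD11b+ cDC (65924) and 73077 in CD8+ cDC. Transcripts of Ifnb1 and Il12a lay at background on all 3 arrays.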
